A study of Mus musculus with 4 samples.

How the data were processed

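Gene expression was measured in the pontine nucleus of ICR mice at 4 ages: embryonic day 17.5 (E17.5) and postnatal days 1, 5 and 14 (P1, P5 and P14). Each age was 1 pool of dissected tissue from 27, 16, 13 and 12 mice, in that order, hybridised to 1 Affymetrix array, so that 68 mice gave 4 arrays and no age had a replicate. Per the labels, total RNA was extracted with Trizol and a column, turned into sense-strand cDNA with a whole-transcript kit and labelled with biotin.

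The deposited values are normalised log2 signals per probe set, made by the authors with Affymetrix Expression Console according to the submitters' processing notes; the version, the summary method and the normalisation are not given in the sources used here. The log2 scale was read from the values themselves, which ran from 1.84 to 14.72 with 2 decimals. The 4 arrays had nearly the same distribution over 35556 probe sets, with medians of 7.91 (E17.5), 7.94 (P1), 7.89 (labelled P5) and 7.92 (labelled P14). No pair of arrays held identical values. The number of arrays, 1 per age, limits the precision of every difference.

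Probe sets were named with the platform's gene table, which listed 23410 of the 35556 probe sets. Of these, 21789 carried 1 gene symbol and 1621 carried several; the other 12146 probe sets were not named by the table used here and were kept out of the gene comparisons. The Entrez gene identifiers of probe sets were looked up in a RefSeq gene table for the mouse assembly GRCm38.p6, used for names alone. For 21698 probe sets with 1 symbol the identifier was found, and no symbol needed an update. Among probe sets with 1 symbol, each of 19938 genes was represented by its probe set with the highest mean over the 4 arrays. A gene was kept when its highest array reached 8.41 on the log2 scale, the median of all single-symbol probe sets over all arrays; 10901 genes passed and 9037 did not. The deposited values were not rescaled.

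The difference between 2 arrays was taken per gene on the log2 scale. With 1 array per age there was no test, p-value or standard error. Genes were counted by size, at a difference of at least 1 on the log2 scale (2-fold). The only error estimate the files allow was the spread between probe sets of the same gene, taken over 645 genes with 2 or more probe sets past the level filter; it holds probe and measurement noise and not the spread between animals or pools. The comparisons fixed before the data were examined were P1 against E17.5, P14 against E17.5, P5 against P1 and P14 against P5. Those of P5 against E17.5 and of P14 against P1 were added after seeing the data. The level filter, the size threshold, the time course classes, the gene lists, the rule for naming genes and the first set of alternatives were fixed at the same point as the 4 comparisons.

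For each of 35 gene lists, the median difference of the members past the filter was placed among 10000 random lists of the same size, drawn from the 10901 genes and matched on mean level in 10 bins. The percentile describes these 4 arrays and is not a p-value. Percentiles above 97.5 or below 2.5 were counted. For lists of genes drawn independently, 1.7 of 34 would lie outside these limits in a comparison. Genes on the same list can vary together, which the random lists do not allow for, so 1.7 is not an expectation for these lists. The lists covered pontine neuron transcription factors, Hox genes, axon guidance and migration, immature neurons and outgrowth, the cell cycle, neural progenitors, synaptic vesicles and release, glutamate receptors and the postsynaptic density, GABA and glycine receptors with chloride transport, GABAergic and glycinergic neurons, monoaminergic neurons, cholinergic and motor neurons, cerebellar neurons, oligodendrocyte precursors, myelin and oligodendrocytes, astrocytes, microglia and macrophages, endothelium, mural and meningeal cells, red blood cells, choroid plexus and ependyma, voltage-gated sodium and potassium channels, calcium channels and buffering, the extracellular matrix of perineuronal nets, mossy fibre synapse organisers, neurotrophins, thyroid hormone response, DNA methylation and Polycomb, cholesterol synthesis, oxidative phosphorylation, glycolysis and lactate, ribosomal proteins, immediate early genes, neurofilaments and the axonal cytoskeleton, and housekeeping genes.

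The genes named in each comparison were the 10 with the largest positive and the 10 with the largest negative difference among genes past the filter, leaving out predicted, unnamed, small RNA and olfactory or vomeronasal receptor genes. For the time course they were the 6 highest transient peaks and the 6 deepest transient troughs, and for each list described, up to 2 members with the largest positive and 2 with the largest negative difference in the comparison described. Barhl1, Pax6, Slc17a6, Slc17a7, Grin2a, Grin2b, Slc12a2, Slc12a5, Gad1, Gad2, Dcx, Mki67, Mbp, Gfap, Hbb-b1, Ttr, Tph2 and Dbh were to be named whatever their values. Genes with a range of at least 1 on the log2 scale were put into classes by the order of ages in the labels. Rising genes never fell by 0.25 or more between neighbouring ages and ended at least 1 above the start, falling genes were the mirror, and a transient peak or trough lay at least 1 above or below both E17.5 and P14. Similarity of arrays was described with Pearson's r and Spearman's rho across genes, which are not independent replicates.

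Tested on simulated arrays, the procedure called 100% of the genes planted at 2.5-, 4- and 8-fold, 0% of those planted at 1.5-fold and 0 of 9874 unchanged genes. The noise simulated for a difference was the mean of a median-based spread between probe sets, which ran from 0.063 to 0.094 over the comparisons. That is smaller than the standard deviations given in the Results. No spread between pools was simulated, so the outcomes check the calculation and not the precision of the real differences. A list of 25 genes planted 0.3 up on the log2 scale lay at the 100th percentile, and at the 71.4th where nothing was planted. The alternatives tried were no level filter, a level filter at the 75th percentile, arrays centred on their medians, quantile normalisation, the mean of all probe sets of a gene, thresholds of 1.5-fold and 4-fold, and random lists not matched on level. After seeing the data, an exchange of the labels P5 and P14, and a filter and probe set choice made without those arrays, were added. Because the array labelled P5 stood out of the order of ages, the labels were kept as deposited and each value is given by the label of its array. The work was done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.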

Results

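RNA from the developing pontine nucleus was profiled at E17.5, P1, P5 and P14. The pontine nucleus is a group of glutamatergic neurons in the ventral pons that relays signals from the cerebral cortex to the cerebellum through mossy fibres. Its neurons are born in the rhombic lip and migrate to the pons before birth, and their axons form synapses in the cerebellum after birth. Each age was a single pool on a single array, without replicates, so all differences below are between single arrays and no test could be run. Of 19938 named genes, 10901 passed the level filter. The standard deviation of a difference attributable to 1 probe set was 0.12 on the log2 scale for P1 against E17.5, 0.14 for P14 against E17.5, 0.18 for P5 against P1 and 0.15 for P14 against P5. A 2-fold difference is therefore several times the spread between probe sets, while the spread between pools of mice could not be measured. The level filter looked at the highest array alone, and background was not measured. Of the genes at least 2-fold apart, the lower value lay under 8.41 in 54 of 120 for P1 against E17.5, 285 of 626 for P14 against E17.5, 544 of 1406 for P5 against P1 and 286 of 726 for P14 against P5; for such genes the size of the difference and its rank are inexact and no fold is given. Where the lower value of a named gene lay under the lower quartile of its array (6.42 to 6.53), levels are given in place of the difference.

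The arrays did not follow the order of their labelled ages. Across the 10901 genes, Pearson's r with the E17.5 array was 0.968 for P1, 0.909 for the array labelled P14 and 0.754 for the array labelled P5 (Spearman's rho 0.966, 0.903 and 0.765). The array labelled P14 was nearest to P1, with r = 0.966 and 160 genes at least 2-fold apart, whereas 1406 genes were at least 2-fold apart between P1 and the array labelled P5. Myelin genes, which are switched on as oligodendrocytes mature, made this plainest: Mog, a myelin surface protein, stood at 7.18 at E17.5, 7.39 at P1, 12.91 on the array labelled P5 and 8.27 on the array labelled P14. Dcx, a microtubule protein of migrating neurons, stood at 12.97, 12.88, 9.79 and 12.14 in the same order. Among 2120 genes with a 2-fold range over the 4 arrays, the value labelled P14 lay between those of P1 and the array labelled P5 in 1825 genes (86.1%). The value labelled P5 lay between those of P1 and the array labelled P14 in 120 (5.66%). The labels are kept as deposited, and every direction given for the arrays labelled P5 and P14 rests on those labels. Only P1 against E17.5 takes its differences from neither array. The level filter, the probe set choice and the matching of random lists used all 4 arrays there too.

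**Figure D1:**
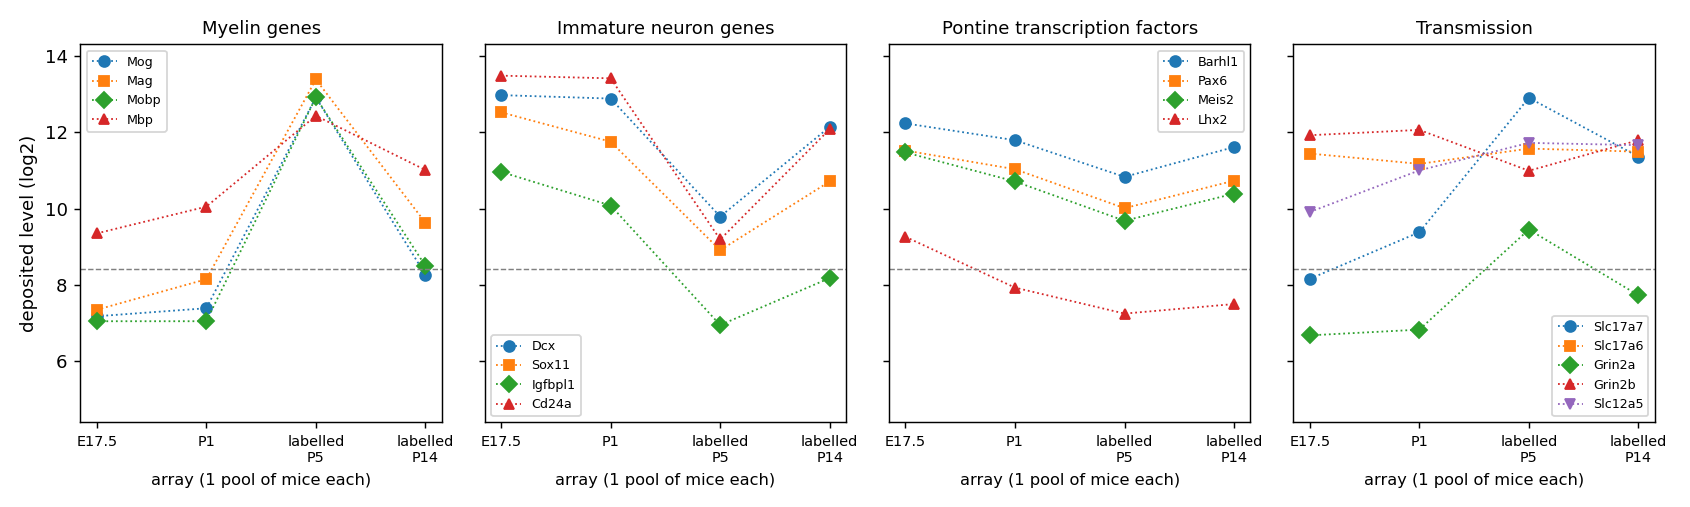
Deposited log2 level (vertical axis) of 17 genes on the 4 arrays (horizontal axis, in the order of their labels), 1 point per gene and array, with dotted lines joining the points of a gene and a dashed line at the level filter of 8.41. Mog, Mag, Mobp and Mbp are highest and Dcx, Sox11, Igfbpl1 and Cd24a lowest on the array labelled P5, where Mog reaches 12.91 and Dcx 9.79.

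Around birth, glial gene lists had higher medians and Hox genes a lower one. Between E17.5 and P1, 90 genes were at least 2-fold higher and 30 at least 2-fold lower, together 1.10% of the genes. The largest positive difference was that of Gfap, the intermediate filament of astrocytes, at 2.70 on the log2 scale. Agt, the angiotensin precursor made by astrocytes, followed at 1.89, with the alarmin Il33 and the lipid droplet protein Cidea at 1.84 each. Lynx1, a modulator of nicotinic receptors (1.62), the lipid carrier Apoe (1.60), Enpp6 of newly forming oligodendrocytes (1.59), the kinase Ptk2b (1.58), and Rasgrp2 and the GABA receptor subunit Gabra5 (1.57 each) completed the 10 largest. Nhlh1, a transcription factor of newly born neurons, stood at 10.02 at E17.5 and at 6.07 at P1. The other genes among the 10 lowest were the corepressor Tle1 (−1.76), the transcription factor Prox1 (−1.75), the vesicle priming factor Cadps2 (−1.74), Lamp5 (−1.67), the retinoic acid receptor Rarb (−1.60), Gstm7 (−1.52), Hoxc5 (−1.48), the retinoic acid binding protein Crabp1 (−1.46) and Pdzrn3 (−1.43).

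All 23 astrocyte genes past the filter were lowest at E17.5. Their median difference at P1 was 0.74, with 6 of 23 at least 2-fold higher. Genes of oligodendrocyte precursors had a median of 0.70, with 2 of 12 at least 2-fold higher, Enpp6 and the receptor Gpr17 (1.13). The myelin list had a median of 0.51 and 3 of 22 members at least 2-fold higher, led by the connexin Gjc3 (1.32) and the carbonic anhydrase Car2 (1.17). Mbp, myelin basic protein, differed by 0.70. The median level of the myelin list was 7.84 at E17.5 and 8.335 at P1, both under 8.41. Members such as Mobp, Mog and Mal lay under that level on both arrays and passed the filter through a later array, so the size of this median is inexact. Microglial genes had a median of 0.49 with no member of 14 reaching 2-fold; the protease Ctss (0.96) and the integrin Itgam (0.77) came nearest. These 4 lists lay above the 97.5th percentile of random lists of like level. In all, 13 of 34 lists with members past the filter lay above that percentile and 3 below the 2.5th.

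Neuronal signalling lists also had medians above 0 at P1, smaller than those of the glial lists, with few members at least 2-fold apart. The synaptic vesicle list had a median of 0.19 over 31 genes, 1 at least 2-fold higher and 1 lower, in which Slc17a7, the vesicular glutamate transporter VGLUT1, differed by 1.22, Syt7 differed by 0.77, and Cadps2 and Sv2b (−0.65) went the other way. Slc17a6, which encodes VGLUT2, stood at 11.44 at E17.5 and 11.17 at P1. Glutamate receptor and postsynaptic density genes had a median of 0.19 over 34 genes, 1 at least 2-fold higher and 1 lower, with Grm7 at 1.47, Gria3 at 0.96, Gria1 at −1.36 and Cacng3 at −0.72. Sodium and potassium channel genes had a median of 0.37 over 25 genes, 1 at least 2-fold higher, among which the potassium channels Kcnma1 (1.00) and Kcnj10 (0.94) led, Kcnj10 being a channel of glia. Calcium channel and buffering genes had a median of 0.31 over 22 genes, 1 at least 2-fold higher, led by the buffer calretinin, Calb2 (1.24), and Ryr2 (0.55). All 4 lists lay above the 97.5th percentile. Axonal cytoskeleton genes did too, with a median of 0.12 over 20 genes, 2 at least 2-fold higher, the tubulin Tuba4a at 1.23 and the surface protein Thy1 at 1.03. In the GABA and glycine receptor list (median 0.07 over 16 genes, 96.6th percentile), Gabra5 and Slc12a5, the chloride extruder KCC2, were at least 2-fold higher; Slc12a5 differed by 1.09, while Slc12a2, the chloride importer NKCC1, stood at 9.88 and 9.76.

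The lists of Hox genes, pontine transcription factors, and GABAergic and glycinergic neurons had medians below 0 at P1. Most members lay within 2-fold: in that order, 2 of 11, 1 of 13 and 1 of 5 past the filter were at least 2-fold lower. The 11 Hox genes past the filter had a median of −0.64, with Hoxc5 and Hoxa5 (−1.07) at least 2-fold lower. The 13 pontine transcription factors had a median of −0.20, with Lhx2 at −1.33 and Meis2 at −0.76; Barhl1, the homeobox factor of rhombic lip derived neurons, differed by −0.44 and Pax6 by −0.49. Of the GABAergic and glycinergic list, 5 of the 16 members named on the array passed the filter, all highest at E17.5, with a median of −0.88 at P1. Over all 16 members the median was −0.28; Gad1 and Slc6a5 passed the filter through their E17.5 value alone. The glycine transporter Slc6a5 differed by −1.24, Lhx1 differed by −0.90, and the GABA synthesis genes Gad1 and Gad2 differed by −0.65 and −0.88. These 3 lists lay below the 2.5th percentile among lists matched on level; the pontine list lay at the 3.48th among lists not matched. Genes of immature neurons lay near the median of all genes (−0.06), with a median of −0.09 over 25 genes and none at least 2-fold apart; Igfbpl1 differed by −0.88 and Sox11 by −0.77. Axon guidance and migration genes had a median of 0.03 over 42 genes (98.4th percentile), none at least 2-fold apart, with Plxna4 at 0.85, Slit1 at 0.78, Dcc at −0.78 and Robo3 at −0.69. The cell cycle list had a median of −0.08 over 20 genes and the neural progenitor list one of 0.05 over 16, again with no member at least 2-fold apart.

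Between E17.5 and the array labelled P14, 496 genes were at least 2-fold higher and 130 at least 2-fold lower (5.74% of the genes). This is the widest span of ages in the labels, and it spans the period in which the nucleus becomes wired to the cerebellum. The 10 largest positive differences were led by Gfap at 4.72, Agt at 3.66, Lynx1 at 3.53, Enpp6 at 3.22 and Slc17a7 at 3.20. Thy1 (2.88), the acute phase gene Serpina3n (2.77), Tuba4a (2.74), Cidea (2.71) and Cpne9 (2.68) followed. Among the 10 lowest, Nhlh1 stood at 10.02 and 6.23, and the others were Igfbpl1 (−2.78), the glypican Gpc2 of growing axons (−2.53), Ebf3 (−2.34), Prox1 (−2.20) and Tle1 (−2.13). Slco5a1 (−1.89), the bombesin receptor Grpr (−1.87), Gstm7 (−1.83) and Sox11 (−1.81) completed them, with Ebf3, Prox1 and Sox11 being transcription factors.

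Glial lists had the largest positive medians here, as they had between E17.5 and P1. The myelin list had a median of 1.37 with 15 of 22 members at least 2-fold higher, led by Gjc3 (2.32) and the myelin glycoprotein Mag (2.28), and Mbp was 3.16-fold higher (1.66). Astrocyte genes had a median of 1.24 with 15 of 23 at least 2-fold higher, oligodendrocyte precursor genes one of 1.23 with 9 of 12, led by Enpp6 and Gpr17 (2.28). Microglial genes had a median of 1.08 with 8 of 14, led by the receptor Csf1r (1.32) and Laptm5 (1.25). No member of these 4 lists was at least 2-fold lower.

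Lists for transmission and excitability had medians above 0 on the array labelled P14 against E17.5, all above the 97.5th percentile, and most members lay within 2-fold. The medians were 0.45 for synaptic vesicles (1 of 31 at least 2-fold higher, 1 lower), 0.38 for glutamate receptors (6 of 34 higher, 1 lower), 0.39 for GABA and glycine receptors (4 of 16 higher) and 0.53 for sodium and potassium channels (9 of 25 higher). They were 0.44 for calcium handling (1 of 22 higher) and 0.37 for the axonal cytoskeleton (5 of 20 higher). Within them, Gabra5 was 4.76-fold higher (2.25), Calb2 4.53-fold (2.18), Slc12a5 3.36-fold (1.75), the glial channel Kcnj10 3.01-fold (1.59), Grm7 2.99-fold (1.58), Kcnma1 2.95-fold (1.56) and Grin2d 2.83-fold. Grin2a, an NMDA receptor subunit that accumulates as synapses mature, differed by 1.05, between levels of 6.68 and 7.73. Both levels lay under 8.41, so the size is inexact, and Grin2a passed the filter through the array labelled P5 alone. Grin2b, the early counterpart of Grin2a, stood at 11.92 and 11.79. Slc17a6 differed by 0.05 and Slc12a2 by −0.20, while Cadps2 (−1.36) and Gria1 (−1.05) were at least 2-fold lower. Among the mossy fibre synapse organisers the median was 0.19 over 19 genes. Within this list Bmp4 differed by 2.48, Cbln2 by 0.98 and C1ql3 by −0.76. The perineuronal net list had a median of 0.28 over 11 genes (95.2nd percentile), with the proteoglycan Bcan at 1.47, the link protein Hapln1 at 1.08 and the hyaluronan synthase Has2 at −0.89. The neurotrophin list had a median of 0.26 over 7 genes (94.3rd percentile), none at least 2-fold apart, with Bdnf at 0.72 and Sort1 at −0.49; without the level filter that median was 0.10.

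Lists that lay below the 2.5th percentile on the array labelled P14 included Hox genes (median −0.78, with 5 of 11 at least 2-fold lower, Hoxa2 at −1.71 and Hoxa5 at −1.68), pontine transcription factors (−0.46, with Lhx2 at −1.76 and Meis2 at −1.08) and immature neurons (−0.31, with 5 of 25 at least 2-fold lower). Barhl1 differed by −0.62, Pax6 by −0.79 and Dcx by −0.83. Axon guidance and migration genes went both ways, with 3 of 42 at least 2-fold higher and 3 lower and a median of −0.18 (7.42nd percentile). The receptor Plxna4 (2.83-fold) and the ligand Slit3 (2.46-fold) were higher, and the receptors Nrp1 (−1.41) and Unc5d (−1.30) were lower.

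The array labelled P5 differed from P1 more than any other pair of neighbouring labels, over 4 days in the labels. In this comparison 977 genes were at least 2-fold higher and 429 at least 2-fold lower (12.9% of the genes), and against E17.5 the counts were 1234 and 600 (16.8%). All but 2 of the 10 largest positive differences belonged to the myelin list: Mobp at 5.86, Mog at 5.52, Mag at 5.23, Cldn11 at 4.83, Mal at 4.21 and Fa2h at 4.19, with Ermn at levels of 5.40 at P1 and 11.12 on the array labelled P5 and Opalin at 6.04 and 10.36. The others were Hapln1, a link protein of perineuronal nets, at levels of 6.13 and 11.30, and Lgi3, at a difference of 4.74. The 10 largest negative differences were those of Cd24a, a surface protein of young neurons (−4.22, 18.6-fold lower), Ablim3 (−3.39), the RNA-binding protein Mex3a (−3.39), the sodium channel Scn9a (−3.37), Igfbpl1 (−3.13), Stk32b (−3.12), Dcx (−3.09, 8.51-fold lower), Gpc2 (−2.98), Lrat (−2.93), an enzyme of retinoid storage, and Crabp1 (−2.90).

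Of the 22 myelin genes past the filter, 21 were at least 2-fold higher on the array labelled P5 than at P1, with a median of 3.65; Mbp differed by 2.38. All 22 had their highest value on that array. Oligodendrocyte precursor genes had a median of 1.19, with Enpp6 at 3.53, Bcas1 at 1.83 and Pcdh15 at −1.22. Astrocyte genes had a median of 0.88, with 10 of 23 at least 2-fold higher, among them the neurotensin receptor Ntsr2 (3.01), the connexin Gjb6 (2.89) and Gfap (2.20). Microglial genes had a median of 0.61, with Itgam (1.14) and Tmem119 (1.09) in the lead. Markers of glia thus differed on this array alongside the neuronal genes given next.

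Genes of young neurons were much lower on the array labelled P5. The immature neuron list had a median of −1.21 against P1, with 14 of 25 members at least 2-fold lower and none higher, led by Cd24a and Igfbpl1, and 24 of the 25 had their lowest value on this array. Axon guidance genes had a median of −0.39, with 9 of 42 at least 2-fold lower and 2 higher. Among them Slit1 (−2.27) and Plxna3 (−1.86) were lower, and Unc5b (1.67) and Slit3 (1.37) were higher. Cell cycle genes had a median of −0.61 over 20 genes, with none at least 2-fold apart. Rrm2 (−0.97) and Mcm6 (−0.88) had the largest negative differences and Mki67, the Ki-67 antigen, differed by −0.77. Neural progenitor genes had a median of −0.38 over 16 genes, with Prom1 at 1.25 and Msi1 at −1.08; without the level filter that median was −0.21. These 4 lists lay below the 2.5th percentile.

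Transmission genes split on the array labelled P5. The synaptic vesicle list had a median of 0.62 against P1, with 11 of 31 at least 2-fold higher, among them Slc17a7 (3.52, 11.5-fold) and Vamp1 (3.38, 10.4-fold); Stx1a (−1.20) and Unc13a (−0.89) were lower. Slc17a6 differed by 0.40. Sodium and potassium channel genes had a median of 0.76, with 8 of 25 at least 2-fold higher and 3 lower; the sodium channel subunit Scn4b (3.18) and the potassium channel Kcna1 (2.94) of mature axons were higher, and Scn3a (−1.52) of young neurons and Kcnd3 (−1.32) were lower. Both lists lay above the 97.5th percentile. Glutamate receptor genes lay at the 73.3rd percentile, with 4 of 34 at least 2-fold higher and 3 lower. Grin2a differed by 2.62, Grm4 differed by 1.66, and Grin2b (−1.07), Shank2 (−1.36) and Grik3 (−1.07) were lower. The GABA and glycine receptor list showed opposite differences in the mature and the fetal glycine receptor subunits, Glra1 (2.20) and Glra2 (−2.09), and Gabrg1 differed by −0.76. Slc12a2 was 2.95-fold higher (1.56) and Slc12a5 differed by 0.72; the list had a median of 0.18 (85.5th percentile). Calcium genes likewise went both ways, with 6 of 22 at least 2-fold higher and 2 lower, Calb2 5.66-fold higher, Cacna2d3 at 1.51, Cacna1h at −1.93 and Cacna1g at −1.09. Perineuronal net genes (median 0.13 over 11) held Hapln1, Hapln4 (3.12), tenascin C or Tnc (−2.62) and Has2 (−1.04), and mossy fibre organisers held Bmp4 (1.78), Cbln1 (−2.14) and Lrrtm4 (−1.18). The axonal cytoskeleton list (median 0.21, 94.0th percentile) held the heavy neurofilament Nefh (3.68, 12.8-fold), Tuba4a (2.57) and Mapt (−1.31). No direction is given for the medians of the glutamate receptor, calcium, mossy fibre and neurotrophin lists here, because centring each array, which moved the median of all genes by −0.11, turned their signs.

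**Figure D2:**
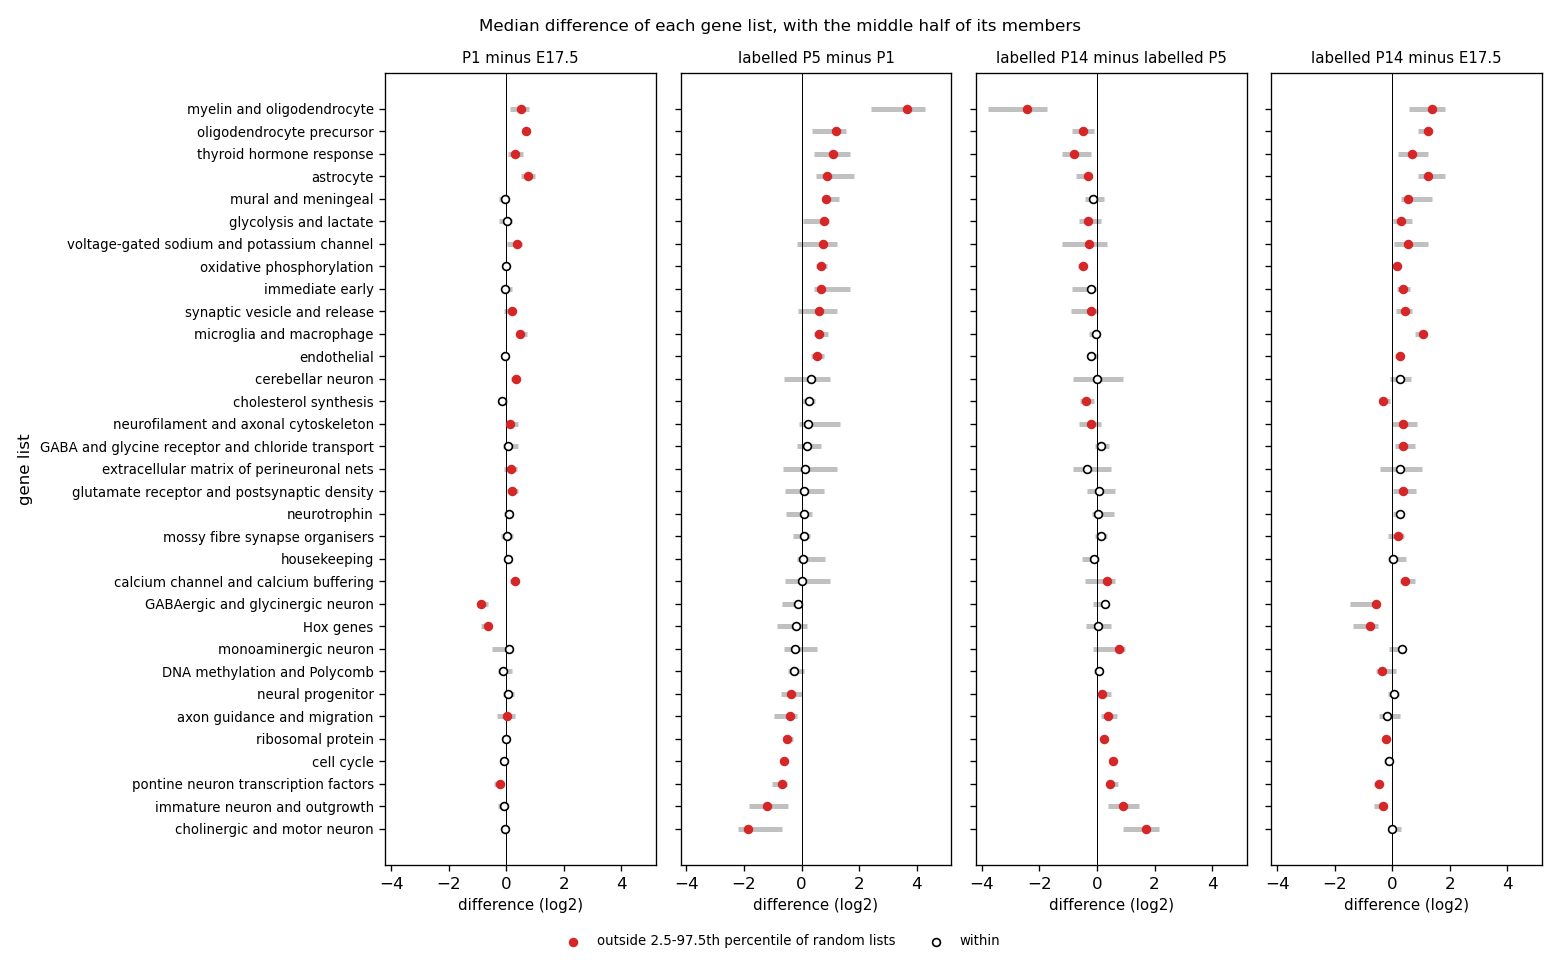
Median log2 difference (horizontal axis) of each gene list with at least 3 members past the level filter (vertical axis) in the 4 comparisons fixed before the data were examined, 1 panel each, with points for medians (red where outside the 2.5th to 97.5th percentile of random lists) and bars from the lower to the upper quartile of the members. The myelin list is farthest from 0 in the panels that hold the array labelled P5, at 3.65 against P1 and −2.43 for P14 minus P5.

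Genes on the pontine transcription factor list were lowest on the array labelled P5. All 13 pontine transcription factors past the filter were highest at E17.5 and lowest on that array, with a median of −0.68 against P1; 7 of 13 were at least 2-fold lower than at E17.5. Meis1 (−1.54) and Nfib (−1.20) had the largest negative differences against P1, and Barhl1 differed by −0.96 and Pax6 by −1.02. The Hox genes went both ways from P1, with Hoxa3 (−1.63) and Hoxa2 (−1.46) lower and Hoxb5 (1.06) and Hoxc5 (0.97) higher, and a median of −0.18 (8.64th percentile).

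From the array labelled P5 to the array labelled P14, the differences ran the other way: 235 genes were at least 2-fold higher and 491 at least 2-fold lower (6.66% of the genes), over 9 days in the labels. The largest negative differences were mostly myelin genes, with Mog at −4.64, Mobp at −4.41, Trf (transferrin) at −3.90, Mal at −3.80 and Mag at −3.75. Ermn stood at 11.12 and 5.96 on these arrays and Opalin at 10.36 and 6.11. Hapln1 (−3.67), Nipal4 (−3.53) and the actin-severing protein Gsn (−3.48) completed the 10. The largest positive differences were those of Ablim3 (3.27), Stk32b (2.96), Cd24a (2.89), the vesicle protein Rab3b (2.84), Camkv (2.74), Crabp1 (2.72), Zfp804b (2.68), Scn9a (2.63), Slc10a4 (2.62), a vesicle protein of cholinergic and monoaminergic neurons, and Slc18a3, the vesicular acetylcholine transporter (2.59). The myelin list had a median of −2.43 with 21 of 22 at least 2-fold lower, and Mbp differed by −1.42. The immature neuron list had a median of 0.92 with 10 of 25 at least 2-fold higher, among them Dcx (2.35, 5.10-fold).

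Other lists were higher on the array labelled P14 than on that labelled P5: cell cycle genes (median 0.56, with Mki67 at 0.78), axon guidance genes (0.38, with Slit1 at 2.18, Plxnd1 at 1.52 and Unc5b at −1.46), pontine transcription factors (0.46, with Meis1 at 1.11, Nfib at 0.79, Barhl1 at 0.78 and Pax6 at 0.72) and calcium genes (0.35, with Ryr1 at 1.22, Cacna1h at 1.21 and Calb2 at −1.56). Lower lists included oligodendrocyte precursor genes (−0.50, with Enpp6 at −1.90), astrocyte genes (−0.32, with Gjb6 at −1.76 and S100b at −1.71), channel genes (−0.29, with Scn4b at −3.03) and synaptic vesicle genes (−0.21, with Vamp1 at −2.78 and Syt2 at −2.28). The last of these lay at the 0.88th percentile among lists matched on level and at the 4.93rd among lists not matched. Of single transmission genes, Slc17a7 (−1.54), Grin2a (−1.72) and Slc12a2 (−1.64) were lower, Grin2b (0.80) was higher, and Slc12a5 differed by −0.06 and Gfap by −0.18. Perineuronal net genes had a median of −0.34 (4.44th percentile; 0.01 without the level filter), with Tnc at 1.90 and Hapln4 at −2.93, and mossy fibre organisers one of 0.14 (96.6th percentile), with Cbln1 at 1.98, Cbln2 at 1.16 and Bmp4 at −0.65.

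Set against P1 instead, the array labelled P14 had 149 genes at least 2-fold higher and 11 at least 2-fold lower (1.47%), in a comparison added after seeing the data. Dcn, the proteoglycan decorin, had the largest positive difference (2.66), followed by Fxyd7 (2.24), Slc6a13 (2.21), the small heat shock protein Hspb1 (2.13) and Cpne9 (2.12). Gfap (2.02), Slc17a7 (1.98), Igf2 (1.92), Lynx1 (1.91) and Thy1 (1.85) completed the 10 largest. The largest negative differences were those of Igfbpl1 (−1.90), Gpc2 (−1.64), Cd24a (−1.33), Mex3a (−1.26) and Mid1 (−1.17). Sostdc1 (−1.12), the Y-linked gene Eif2s3y (−1.09), Sox11 (−1.04), Ebf1 (−0.99) and Ebf3 (−0.98) completed the 10 lowest. In this comparison the medians included 0.79 for the myelin list, 0.65 for mural and meningeal genes (6 of 15 at least 2-fold higher), 0.525 for oligodendrocyte precursors and 0.50 for astrocytes. They also included 0.28 for synaptic vesicles, 0.30 for calcium genes, −0.16 for immature neurons, −0.20 for cholesterol synthesis and −0.26 for pontine transcription factors.

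**Figure D3:**
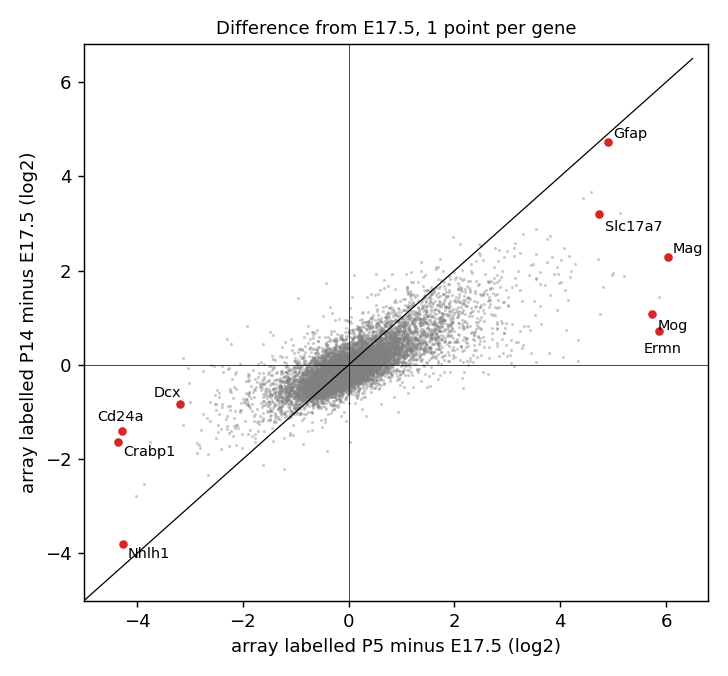
Difference from E17.5 on the log2 scale for each gene past the filter (1 grey point per gene), with the array labelled P5 on the horizontal axis and the array labelled P14 on the vertical axis, the line of equal differences drawn, and 9 genes in red. Mog lies at 5.73 and 1.09 and Dcx at −3.18 and −0.83, nearer to 0 on the vertical axis, while Gfap (4.90 and 4.72) lies near the line; both axes share the E17.5 array.

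Endothelial genes had medians of −0.06 at P1 and 0.27 on the array labelled P14, each against E17.5, and of 0.53 on the array labelled P5 against P1. The transporter Slc16a1 differed by 1.03, 2.14 and 1.28, Itm2a by 0.71 on the array labelled P14 and Emcn by 0.97 on the array labelled P5. Mural and meningeal genes had medians of −0.05, 0.56 and 0.85 in the same comparisons, with Dcn at 2.57 and the transporter Slc6a13 at 1.98 on the array labelled P14, and Slc6a13 at 2.23 and Dcn at 2.19 on the array labelled P5. Of 12 red blood cell genes 6 were named on the array and 1 passed the filter, Alas2, at 8.89, 8.41, 8.66 and 8.62 in the order of the labels. None of the 13 choroid plexus and ependyma genes passed. Ttr of the choroid plexus stood between 5.93 and 6.59, Hbb-b1 was not named by the table used here, and the serotonin and noradrenaline synthesis genes Tph2 (7.17 to 8.02) and Dbh (6.08 to 6.21) lay under the filter.

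Of the monoaminergic list 3 of 9 members named on the array passed the filter, each with its highest value on a different array. Their median level was 8.43 at E17.5, 7.32 at P1, 7.80 on the array labelled P5 and 7.86 on that labelled P14. Where a value lay under 8.41, the size of the difference is inexact. Th, tyrosine hydroxylase, differed by −1.11 at P1 from E17.5, Ddc by 1.33 and the serotonin transporter Slc6a4 by −0.99 on the array labelled P5 from P1, and Slc6a4 by 1.21 and Ddc by −1.05 from the array labelled P5 to that labelled P14. Of the cholinergic and motor neuron list 3 of 8 passed. The acetylcholine and choline transporters Slc18a3 and Slc5a7 differed by −2.52 and −1.87 on the array labelled P5 from P1, and Ret differed by 0.53. On the other 3 arrays Slc18a3 stood between 9.93 and 10.01. Of the cerebellar neuron list 4 of 8 passed, with a median of 0.36 at P1 against E17.5 (Rora at 0.40, Car8 at 0.38) and one of 0.26 on the array labelled P14 against E17.5; without the level filter these were 0.15 and 0.12. Between P1 and the array labelled P5 the list held Calb1 at −2.59 and Pvalb, at levels of 6.48 and 8.55, around a median of 0.33 (70.8th percentile). The GABAergic and glycinergic list had medians of −0.57 on the array labelled P14 against E17.5 (−0.23 without the level filter), with Slc6a5 at −1.47, Gad1 at −0.34 and Gad2 at −0.57, and of −0.13 on the array labelled P5 against P1, with no member at least 2-fold apart.

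Over the time course as labelled, 2120 genes had a 2-fold range. Of these, 187 were in the rising class and 51 in the falling class, 456 had a transient peak and 181 a transient trough. Every peak and trough lay on the array labelled P5; the remaining 1245 genes fitted no class. The 6 highest peaks were Ermn, Mog, Mobp, Opalin, Trf and Mal, all on the myelin list; Mog lay 4.64 and Mal 3.80 above the nearer of E17.5 and P14. The 6 deepest troughs were Ablim3 (3.13 below), Stk32b (2.96), Cd24a (2.89), Crabp1 (2.72), Scn9a (2.63) and Slc10a4 (2.62). For 626 genes at least 2-fold apart between E17.5 and the array labelled P14, the step with the largest change in the direction of that difference was found. It was from E17.5 to P1 in 179 and from P1 to the array labelled P5 in 418. In 29 it was from the array labelled P5 to that labelled P14. A step against that direction was not counted, however large. With the labels P5 and P14 exchanged, an alternative added after seeing the data, the classes held 1148 rising and 556 falling genes, 14 peaks and 4 troughs.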

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

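With 1 array per age, no spread between pools could be set against any alternative, and background was not measured; in 38.7% (P5 minus P1) to 45.5% (P14 minus E17.5) of the genes at least 2-fold apart in the 6 comparisons, the lower value lay under the filter's level, where the size of a difference is inexact. Centring each array on its median, quantile normalisation and the mean of all probe sets of a gene left the 12 counts of genes at least 2-fold apart, the 4 time course classes and the 12 counts of lists outside the percentile limits within 1.5 times their values. Centring moved the median of all genes by at most −0.12 (P5 minus E17.5). Among 204 list medians, 5 moved by more than the spread between probe sets under centring, 5 under quantile normalisation and 0 with the mean of probe sets; without the level filter 25 moved and another reversed, where reversed means a change of sign in a median that lay outside the percentile limits. Counting medians within those limits too, 13 of 204 changed sign under centring, 10 under quantile normalisation, 3 with the mean of probe sets and 12 without the level filter. With random lists not matched on level, 195 of 204 lists kept their side of the percentile limits, 7 no longer lay outside them and 2 newly did. Among 214 values of named genes, 0 moved under centring, 1 with the mean of probe sets and 2 under quantile normalisation. The 0 was fixed in advance: centring shifts all genes of a comparison alike, by less than its spread between probe sets. Such a shift also moves the random lists alike, so the counts of lists outside the percentile limits could hardly change under centring.

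The counts followed the size threshold by construction. Higher and lower genes at 1.5-fold numbered 1166 and 822 for P14 minus E17.5, 418 and 227 for P1 minus E17.5, 2096 and 1232 for P5 minus P1, 780 and 1362 for P14 minus P5, 2195 and 1653 for P5 minus E17.5, and 512 and 125 for P14 minus P1. At 4-fold they numbered 48 and 6, 1 and 1, 222 and 52, 24 and 85, 330 and 84, and 6 and 0, in that order. A level filter at the 75th percentile left fewer genes and moved 6 counts by over 1.5 times: lower genes to 75 for P14 minus E17.5, 13 for P1 minus E17.5, 307 for P14 minus P5 and 7 for P14 minus P1, and higher genes to 622 for P5 minus P1 and 762 for P5 minus E17.5. Without a level filter, 17 genes were lower for P14 minus P1. Pearson's r was then 0.991 for E17.5 with P1, 0.946 with the array labelled P5 and 0.978 with that labelled P14, 0.957 and 0.991 for P1 with those arrays, and 0.974 between them; r was higher for all 6 pairs, and the cause was not tested.

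The alternatives added after seeing the data were an exchange of the labels P5 and P14, and a level filter and probe set choice without those arrays. The exchange gave 1234 higher and 600 lower genes for P14 minus E17.5, 149 and 11 for P5 minus P1, and classes of 1148 rising and 556 falling genes, 14 peaks and 4 troughs. Of 68 list medians in these comparisons, 43 moved, 21 did not and 4 reversed in that sense (9 changed sign in all): neural progenitors (P5 minus P1) to 0.025, cholinergic and motor neurons (P5 minus P1) to 0.07, mossy fibre synapse organisers (P14 minus E17.5) to −0.04 and cholesterol synthesis (P14 minus E17.5) to 0.18. These follow from which array bears which label. Without a level filter the GABAergic and glycinergic median for P14 minus P1 reversed to 0.055; the cause was not tested. With the filter and probe sets chosen without the arrays labelled P5 and P14, both counts of P1 minus E17.5 stayed within 1.5 times their values and 3 of 34 list medians moved. No paired analysis was possible because each age was 1 pool on 1 array.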

Other observations

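The tests of explanations for the 3 patterns below (array order, meningeal genes and cholinergic transport genes), the sets of meningeal and motor neuron genes used in them and the comparison of P14 against P1 were chosen after those patterns had been seen. Energy metabolism genes set the array labelled P5 apart. All 35 oxidative phosphorylation genes past the filter were highest on it, with a median of 0.69 against P1, 6 members at least 2-fold higher and the complex I subunits Ndufb8 (1.24) and Ndufa2 (1.20) in the lead; the array labelled P14 had a median of −0.49 against it and of 0.15 against E17.5. Glycolysis genes had a median of 0.79 on the array labelled P5 against P1, with the neuronal enolase Eno2 at 1.94, Ldhb at 1.52 and Pfkp at −0.50, and one of −0.32 from that array to the array labelled P14. Ribosomal protein genes went the other way, with a median of −0.51 on the array labelled P5 against P1 and 24 of 25 members lowest there, led by Rps20 (−0.95) and Rpl24 (−0.71). Cholesterol synthesis genes had a median of −0.32 on the array labelled P14 against E17.5 and of 0.27 on the array labelled P5 against P1. The sterol isomerase Ebp (2.22) and the neuronal cholesterol hydroxylase Cyp46a1 (1.33) led the latter. The 12 housekeeping genes had a median of 0.05 at P1 and of 0.04 on the array labelled P14, each against E17.5, and the latter turned its sign when arrays were centred; B2m was 2.55-fold higher (1.35) on the array labelled P14.

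Hormone response and activity genes also differed. The 4 thyroid hormone response genes past the filter had a median of 1.08 on the array labelled P5 against P1, with Klf9 at 2.34 and Hr at 1.47, and of 0.69 on the array labelled P14 against E17.5, with Klf9 at 1.65 and the thyroxine transporter Slco1c1 at 1.10; without the level filter these medians were 0.69 and 0.27. Immediate early genes, which follow neuronal activity and also handling, had a median of 0.67 on the array labelled P5 against P1, with Fos at 2.21 and Arc at 2.05, and of 0.38 on the array labelled P14 against E17.5, with Fos at 1.36, Nr4a1 at 0.99 and Ier5 at −1.04; without the level filter these were 0.43 and 0.25. The DNA methylation and Polycomb list had a median of −0.35 on the array labelled P14 against E17.5, where Ezh2 was 2.22-fold lower (−1.15), Cbx2 differed by −0.74 and Dnmt3a by 0.82. Neurotrophin genes had a median of 0.10 at P1 against E17.5, which turned to −0.06 without the level filter, with Bdnf at 0.30.

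The array labelled P5 lay farther from E17.5 and P1 than the array labelled P14 did. Myelinated tract tissue in the pool labelled P5, as the whole cause, would dilute neuronal genes alike. Against this, the synaptic vesicle median exceeded the immature neuron median by 1.13 in P5 minus P14 (95% interval over genes 0.68 to 1.79). These 2 medians are part of the pattern itself, and the interval spans genes, which are not independent, and not pools. Tract tissue as a part of the cause stays open. An exchange of the 2 labels stays open, since the list medians that raise it are the pattern itself. Of 974 genes at least 0.5 apart between E17.5 and P1 on the log2 scale, 969 differed between the arrays labelled P14 and P5. Of these 969, 49.3% went on in the same direction from the array labelled P14 to that labelled P5. The 95% interval over genes was 46.2 to 52.4, which favours neither order. From P1, 76.8% of the 974 genes went on in the same direction on the array labelled P14 and 61.0% on that labelled P5. Both of these shares hold the P1 value that picked the genes, and neither sets the 2 arrays against each other. A true developmental peak at P5, and a difference between the pools in dissection or age, were not tested and stay open.

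Meningeal genes were higher on the arrays labelled P5 and P14 than at P1, with medians of 1.20 and 1.27. These 7 genes are on the mural and meningeal list, 4 of them (Col3a1, Col6a3, Dcn and Slc6a13) passing the filter through those arrays alone, and they differed by 0.38 to 2.23 on the array labelled P5 and by 0.54 to 2.66 on that labelled P14; Igf2 stood at 9.65 at P1 and at 10.85 and 11.57 on those arrays. Meningeal tissue in the later pools stays open. Of 23 other meningeal genes, on none of the lists, 3 reached the filter's level at E17.5, too few to decide. Their medians against P1 were −0.17 on the array labelled P14 and −0.45 on that labelled P5. Over all 23, of which 20 lay under that level at P1, medians went the other way. They were 0.31 on the array labelled P14 (−0.31 to 1.60) and 0.76 on that labelled P5 (−0.69 to 1.75). A higher share of blood vessels cannot be told apart from meningeal tissue. The meningeal median exceeded the endothelial one by 0.97 on the array labelled P14 (95% interval over genes 0.63 to 1.95). On the array labelled P5 the excess was 0.68, with an interval from −0.22 to 1.81. Growth of the meninges with age is a biological alternative that was not tested.

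The cholinergic transport genes Slc18a3 and Slc5a7 were lower on the array labelled P5 than on the other 3 arrays. A lower share of neurons as the whole cause would lower all neuronal genes, and the synaptic vesicle median against P1 was 0.62, above 0 by more than the spread between probe sets. The immature neuron and pontine transcription factor medians were −1.21 and −0.68, so a lower share of neurons together with changes in expression per neuron stays open. Fewer motor neurons in that pool cannot be told apart from lower expression per cell, because 0 of 3 motor neuron transcription factors (Isl1, Isl2 and Mnx1) passed the level filter, the highest level being 7.20. A change with age in the cholinergic cells themselves was not tested.

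Several single genes were noted after their values were seen. The Y-linked genes Kdm5d, Uty and Eif2s3y stood at 8.50, 8.41 and 9.60 at E17.5, 8.25, 8.54 and 9.69 at P1, 7.53, 7.75 and 8.57 on the array labelled P5, and 7.51, 7.90 and 8.60 on that labelled P14. Xist stood at 12.48, 12.60, 12.16 and 12.57 in the same order. Hspb1 was highest on the array labelled P14, at 10.19, against 8.78 on the array labelled P5 and 8.06 at P1. Gabra6, a marker of cerebellar granule cells, stood under the filter at 8.34 on the array labelled P5 and at 6.34 on that labelled P14. Some probe sets were left out of the gene comparisons because the table used here did not list them or gave them several symbols. Of these, 4693 passed the filter's level. On the array labelled P5, 108 were at least 2-fold higher than at P1 and 212 at least 2-fold lower. At P1, 28 were at least 2-fold higher and 3 at least 2-fold lower than at E17.5.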
